A study of Rattus norvegicus with 9 samples.

How the data were processed

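Whole liver RNA was sequenced from 9 Sprague-Dawley rat liver samples, 3 in each of 3 groups. The normal livers had received neither carbon tetrachloride (CCl4) nor an injection. The PBS livers came from cirrhotic rats injected with phosphate-buffered saline, and the HepLPC livers from cirrhotic rats injected with rat hepatocyte-derived liver progenitor-like cells. Per the labels, the animals were 5 months old and wild type, total RNA was isolated with TRIzol and treated with DNase I, and libraries were made with a TruSeq RNA kit for Illumina HiSeq or NovaSeq instruments. The labels number the replicates of each group 1 to 3 without stating that each number is a separate animal, so p-values measure the spread between these samples, part of which may be technical. Group and replicate were both taken from the sample titles.

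Per the file headers, the deposited values are RPKM, reads per kilobase of gene model per M reads, in 40154 gene rows per library. The submitters' processing notes list HISAT2, StringTie and the human build hg19, while the rows carry rat gene symbols. The build and annotation behind the deposited RPKM values are therefore uncertain, no coordinates are given, and the handling of reads shared between paralogs is not given in the sources used here. Values of near-identical families (the Cyp2c, glutathione transferase, major urinary protein, mast cell protease, haemoglobin and RT1 genes) are uncertain for that reason. A gene table of the rat assembly GRCr8 was used for names only, and 23776 rows matched a symbol or synonym in it. In all, 15120 rows were at 0 in every library.

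The sequencing depth was worked out from the RPKM values, which are whole reads scaled by library and gene length. Whole reads were recovered, within a tolerance of 0.01 read, for 20959 of the 20959 genes above 0 in 3 or more libraries, and 99.8% of the lengths that this gave were whole numbers of bases within 0.01. On simulated data the same step recovered 1997 of 2000 genes exactly. A further 4075 genes above 0 in 1 or 2 libraries were left out of this step. Recovered reads, in megareads (M), ranged from 17.4 to 21.8 M per library, and the RPKM of a library summed to between 561769 and 679882. No replicate pair was alike within sampling noise.

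Because the files hold RPKM and no counts, the test was the one written beforehand for normalized values: limma (lmFit and eBayes with a mean-variance trend, 2-sided) on log2(RPKM + 1), for the 11124 genes with at least 1 RPKM in 3 or more libraries. All 9 libraries entered 1 model with a term per group, which leaves 6 residual degrees of freedom, and each comparison was a contrast of 2 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 11124 genes. Fold changes are differences of mean log2(RPKM + 1) and understate the change of genes with low RPKM. On simulated data with 200 changed genes, limma called 43.9% of 2-fold and 84.7% of 4-fold changes for PBS against normal, with 3 calls among unchanged genes. For HepLPC against PBS it called 42.3% and 83.7%, with 10 such calls, and for HepLPC against normal 49.5% and 84.8%, with 6. No simulated gene was called in the wrong direction, a count of 0 in each comparison. These simulated genes varied independently, so deviations shared across genes within a library were left out. In 100 draws of the libraries' own permuted residuals with no effect, the median was 0 calls in each of the first 2 comparisons. The highest were 2950 for PBS against normal and 3012 for HepLPC against PBS. Of these draws 2 and 5 reached the observed counts of 1262 and 341.

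Before the data were examined, 42 gene lists were fixed: 15 of cell type markers and 27 of pathways and functions, 787 list members in all, of which 6 matched no row and 1 was ambiguous. Lists with 5 or more tested members (38) were tested with camera, which compares a list with all other tested genes, at its preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which tests whether a list moves 1 way on balance without comparing it with other genes, were alternatives. Called members were also counted with p-values adjusted over the list alone. Differences between lists were not tested, except between the marker scores of cell types. The lists share some genes, so their counts are not independent.

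The genes named in the text follow a rule written at the same time. It takes the 10 largest rises and 10 largest falls among called genes for PBS against normal and for HepLPC against PBS, and the 5 largest for HepLPC against normal. These needed groups whose values did not overlap, a mean of at least 1 RPKM in the higher group and a symbol that was not a placeholder. To these were added up to 4 members per list, the 10 opposite-direction genes with the smallest larger adjusted p, and a fixed panel of fibrosis, duct, hepatocyte and apoptosis genes. Of the panel, Mmp9, Mmp13 and Bcl2 were below the filter and not tested. Some genes that the rule names are not reported here. Where a gene outside the rule is named, the text says so.

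The alternatives written beforehand were other pseudocounts, quantile normalization, other filters on low values, a fit of only the 2 groups compared, stricter thresholds, a replicate block, leaving out each library in turn, and the list tests above. Chosen after seeing the data were limma-voom on the recovered reads with library totals or with median-of-ratios scaling, RPKM rescaled by the median of ratios, removal of each library's trend on gene length, and leaving out the 2 libraries with a strong trend. Simulated draws of permuted residuals measured what the PBS libraries shared by 2 comparisons give by chance. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.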

Results

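Gene expression was measured by RNA sequencing in whole livers of 3 groups of rats, with 3 libraries per group. Normal livers came from rats given neither CCl4, a hepatotoxin used to cause cirrhosis, nor an injection. PBS livers came from cirrhotic rats injected with saline, and HepLPC livers from cirrhotic rats injected with hepatocyte-derived liver progenitor-like cells. Depth was 19.9, 21.8 and 21.5 M recovered reads in normal replicates 1 to 3, 17.8, 20.6 and 19.7 M in PBS and 19.3, 19.3 and 17.4 M in HepLPC. Levels are given as mean RPKM ± SD (n = 3 throughout), changes as log2 fold change with its standard error (SE) on log2(RPKM + 1), and adjusted p from limma.

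PBS replicate 1 and HepLPC replicate 2 differed from the other 7 libraries in how their values related to gene length. Their deviation from the group mean fell with length across genes, with a Spearman correlation of -0.564 in PBS replicate 1 and -0.528 in HepLPC replicate 2. It lay between -0.157 and 0.423 in the other libraries. Deviations sum to 0 within a group, so a fall in 1 library brings opposite values in the others of its group. Genes are not independent replicates, so these correlations describe single libraries.

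**Figure D1:**
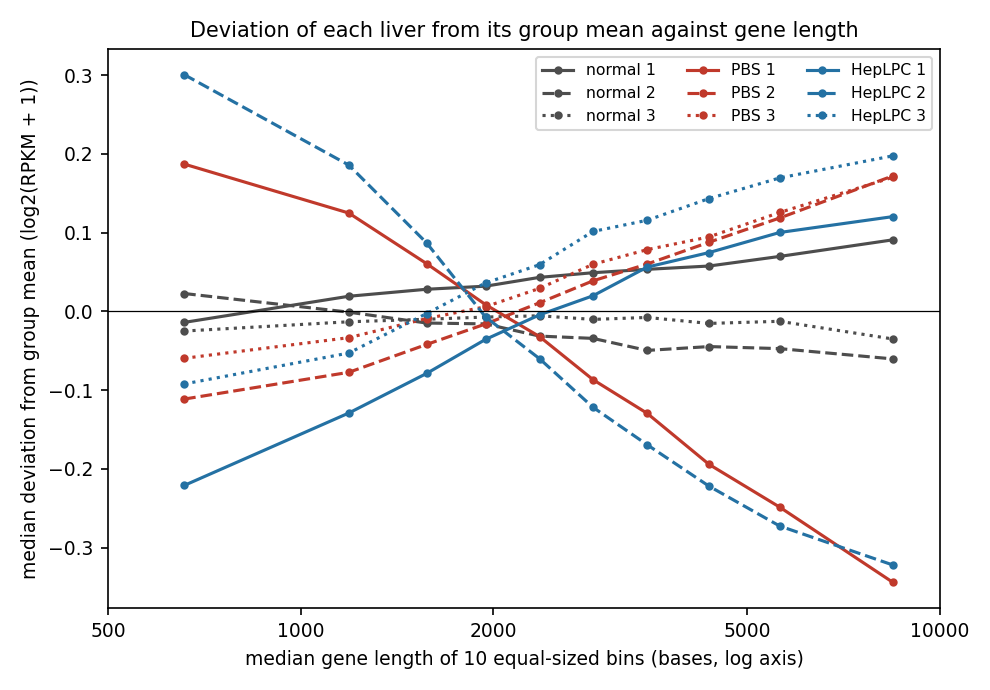
Median deviation of each liver from its group mean, in log2(RPKM + 1), in 10 bins of genes of equal number against the median gene length of the bin in bases (log axis), 1 line per liver. PBS replicate 1 and HepLPC replicate 2 fall with length, with Spearman correlations of -0.564 and -0.528 across genes.

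The 1st comparison, PBS against normal livers, asked how the injured liver differed from the healthy one. The normal rats also had no injection, so effects of injury and of the injection cannot be told apart. Scar matrix and duct genes were far higher in the PBS livers. Col1a1, a chain of type I collagen, was at 0.261 ± 0.0866 RPKM in normal and 7.18 ± 3.32 RPKM in PBS livers (log2 fold change 2.61, SE 0.32, adjusted p = 0.00113). Mgp, matrix Gla protein, an inhibitor of calcification, rose from 8.52 ± 1.24 to 168 ± 29.9 RPKM (4.14, SE 0.22, adjusted p = 6.36e-05). Spp1, osteopontin, rose from 0.586 ± 0.589 to 34.7 ± 30.5 RPKM (4.21, SE 0.58, adjusted p = 0.00208).

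Of 21 tested genes of the fibrillar collagen and scar matrix list, 16 rose and 5 did not pass (20 rose adjusted over the list alone), with camera adjusted p = 3.61e-12 and adjusted p = 0.122 with an estimated correlation. Col3a1 and Sparc rose by 2.20 and 1.06. Matrix proteases and their inhibitors had 6 of 14 members higher (8 adjusted over the list alone; camera adjusted p = 0.000228, adjusted p = 0.225 with an estimated correlation). Among them were the gelatinase Mmp2 (1.89), the macrophage elastase Mmp12 (1.89) and the inhibitors Timp1 (1.89) and Timp2 (2.02). Of 13 myofibroblast markers 9 rose (11 adjusted over the list alone; camera adjusted p = 8.18e-07, adjusted p = 0.0816 with an estimated correlation), among them Loxl1 (1.71), S100a6 (2.74), Vim (1.62) and Acta2, smooth muscle actin (1.19, SE 0.24, adjusted p = 0.0126). Of 13 stellate cell markers 3 rose, both over all genes and adjusted over the list alone: Cygb (1.86), Des (0.89) and Pdgfra (0.78), and the list did not pass camera (adjusted p = 0.318). The Pdgfra call was lost in 15 of 22 alternatives. Lrat, an enzyme of vitamin A storage in stellate cells, was at 8.02 ± 1.01 and 11.9 ± 3.64 RPKM (adjusted p = 0.246). TGF-beta signalling had 7 of 22 members higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0436, adjusted p = 0.638 with an estimated correlation), with Ltbp2 (1.55), Tgfb3 (1.43) and Tgfb2 (1.05) among the higher.

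Duct markers rose almost as a whole: 13 of 14 tested genes of the cholangiocyte and ductular reaction list were higher, also adjusted over the list alone (camera adjusted p = 7.58e-11, adjusted p = 0.124 with an estimated correlation). Krt19, a keratin of bile ducts, was at 0.644 ± 0.291 and 15.9 ± 13.6 RPKM (3.06, SE 0.47, adjusted p = 0.00372), Sox9, a transcription factor of duct cells, at 0.0747 ± 0.0355 and 2.51 ± 0.54 RPKM (1.70), and Cd24 rose by 3.38. The list's median in PBS replicate 1 lay -0.494 from the group mean on the log2 scale, and in PBS replicate 2 0.479. Fetal liver and progenitor genes had 5 of 8 members higher (6 adjusted over the list alone; camera adjusted p = 3.92e-05, adjusted p = 0.077 with an estimated correlation), among them Sox4 (2.06), Gpc3 (2.08) and Tspan8 (2.80), while the fetal albumin relative Afp was at 10.9 ± 0.46 and 13.7 ± 1.52 RPKM (adjusted p = 0.338).

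Of the blood-derived cell lists, recruited and scar-associated macrophages had 7 of 11 markers higher (10 adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.0816 with an estimated correlation). Gpnmb rose by 1.99, Cd9 by 1.79 and Lyz2 by 2.46. None of 13 Kupffer cell markers, the resident macrophages, passed (0 called, also adjusted over the list alone; camera adjusted p = 0.232), and Clec4f was at 72.7 ± 8.67 and 111 ± 22.9 RPKM (adjusted p = 0.0605). In the list of neutrophils and mast cells 4 of 6 rose (6 adjusted over the list alone; camera adjusted p = 0.000307, adjusted p = 0.077 with an estimated correlation), with the mast cell proteases Mcpt2 (3.09) and Cpa3 (2.07) leading. MHC class II genes rose in 5 of 7 cases (7 adjusted over the list alone; camera adjusted p = 0.000865, adjusted p = 0.226 with an estimated correlation), with RT1-Da at 1.13 and Cd74 at 1.16. Of 19 chemokines and cytokines 4 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.44), with Ccl21 (3.53) and Cxcl16 (1.68) among the higher.

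Genes of the antioxidant response governed by the transcription factor NRF2 rose in 16 of 21 cases (18 adjusted over the list alone; camera adjusted p = 2.44e-09, adjusted p = 0.122 with an estimated correlation). The glutathione transferase Gstp1 rose from 16.6 ± 1.87 to 760 ± 580 RPKM (5.06, SE 0.55, adjusted p = 0.000718) and the aldo-keto reductase Akr1b8 from 1.20 ± 0.737 to 113 ± 78.8 RPKM (5.40, SE 0.63, adjusted p = 0.00102). Of 21 proliferation genes 20 rose (21 adjusted over the list alone; camera adjusted p = 3.96e-14, adjusted p = 0.0896 with an estimated correlation): Mki67 was at 0.243 ± 0.0602 and 1.92 ± 0.464 RPKM (1.22, SE 0.15, adjusted p = 0.00136), and Cdk1 and Top2a rose by 2.10 and 1.70. Of 23 pro-apoptotic genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.44): the death receptor Tnfrsf10b (0.78), its ligand Tnfsf10 (0.75) and Diablo (0.48). This count was 1 after rescaling RPKM by the median of ratios, and alternatives lost the calls of Diablo in 13 of 23 cases and Tnfrsf10b in 11 of 22. Of 12 anti-apoptotic genes 2 rose (4 adjusted over the list alone; camera adjusted p = 0.426), Bcl2a1 (0.82) and Bag3 (0.63), and the count was 0 after the same rescaling, with the Bag3 call lost in 13 of 23 alternatives. None of 16 p53 targets passed, also adjusted over the list alone (0 called), while the list lay below the other genes (camera adjusted p = 0.00166, adjusted p = 0.122 with an estimated correlation). Fry, which does not set a list against the other genes, placed the stellate, pro-apoptotic and anti-apoptotic lists higher in PBS livers (adjusted p = 0.00285, 0.0101 and 0.043).

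Several hepatocyte lists lay below the other genes with few single genes called, while pericentral genes and cholesterol synthesis did not pass camera. In fatty acid oxidation and ketogenesis 5 of 25 genes fell (6 adjusted over the list alone; camera adjusted p = 5.73e-13, adjusted p = 0.0816 with an estimated correlation), with Acsl1, an acyl-CoA synthetase, at 493 ± 2.23 and 304 ± 51.4 RPKM (-0.71, SE 0.17, adjusted p = 0.0256). In lipogenesis 1 of 17 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 3.64e-09, adjusted p = 0.122 with an estimated correlation): Scd, the main liver desaturase, by -1.56, against Scd2 at 1.97. Cytochrome P450 drug metabolism had 2 of 23 lower and 1 higher, the same counts as adjusted over the list alone (camera adjusted p = 2.02e-06, adjusted p = 0.0896 with an estimated correlation), with Cyp2c11, a P450 of male rats, at 1173 ± 193 and 346 ± 221 RPKM (-1.93, SE 0.38, adjusted p = 0.0116). Of 16 periportal hepatocyte genes 2 fell (3 adjusted over the list alone; camera adjusted p = 4.11e-08, adjusted p = 0.077 with an estimated correlation), Hsd17b13 by -1.08 and Cyp2f4 by -0.62. Of 17 pericentral genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.677), with the ammonium transporter Rhbg at 2.41. None of 24 genes for secreted proteins and coagulation passed, also adjusted over the list alone (0 called; camera adjusted p = 2.44e-06, adjusted p = 0.077 with an estimated correlation), and albumin (Alb) differed by -0.15 (SE 0.23, adjusted p = 0.728). Of the urea cycle and amino acid genes 1 of 25 fell, Agxt, at -0.78, a call lost in 13 of 23 alternatives (0 adjusted over the list alone; camera adjusted p = 3.45e-08, adjusted p = 0.122 with an estimated correlation).

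Cholesterol synthesis had 5 of 24 genes higher (9 adjusted over the list alone; camera adjusted p = 0.0959), among them Idi1, an isomerase of the pathway (1.51). In bile acid synthesis and transport 3 of 23 rose, also adjusted over the list alone: Cyp7a1, the rate-limiting enzyme of bile acid synthesis (2.18, SE 0.55, adjusted p = 0.0338), and the exporters Abcc3 (2.71) and Abcc4 (0.72). Alternatives lost the call of Cyp7a1 in 14 of 23 cases and that of Abcc4 in 16 of 22. The mean of the bile acid list was positive (0.14) while its median (-0.07) was negative and camera placed it below the other genes (adjusted p = 0.00446, adjusted p = 0.122 with an estimated correlation), a placing lost after rescaling (adjusted p = 0.134). With quantile normalization camera no longer placed that list (adjusted p = 0.52) or secreted proteins and coagulation (adjusted p = 0.405) below the other genes. The remaining genes among the largest changes were higher Aldh3a1, an aldehyde dehydrogenase (5.75, SE 0.57), Defb1, a beta-defensin (4.68), Car2, a carbonic anhydrase (4.62), Serpinb1a (4.53), Cyp2c24 (4.05) and Gpx2 (4.03). Lower were Lrtm2 (-2.61, SE 0.37), Lyc2 (-2.29), the apolipoprotein Apoa4 (-2.25), the elastase Cela1 (-2.13), Rgs16 (-1.84), Plekhb1 (-1.81), Irs3 (-1.63) and Olr59 (-1.39).

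In all, limma called 1262 of 11124 genes between PBS and normal livers, 1157 higher and 105 lower. The groups' values did not overlap for 37.7% of genes, against 10% by chance. The median log2 fold change of all genes was 0.184, so the lower group lists are read against a positive shift. After rescaling by the median of ratios, 806 genes were called, 530 higher and 276 lower, and 3168 without PBS replicate 1 and HepLPC replicate 2. Leaving out normal replicate 1, 2 or 3 gave 668, 620 and 651 calls, and leaving out PBS replicate 3 gave 562.

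The 2nd comparison, HepLPC against PBS livers, asked what the injected cells changed in the cirrhotic liver. Most called genes were lower after the cells, among them duct, scar and antioxidant genes. Gpx2, a glutathione peroxidase, was at 19.3 ± 1.4 RPKM in PBS and 1.69 ± 1.55 RPKM in HepLPC livers (-3.07, SE 0.32, adjusted p = 0.00248). Mgp fell to 29.7 ± 9.68 RPKM (-2.49, SE 0.22, adjusted p = 0.00177) and Lcn2, lipocalin 2 of the acute phase, from 21.4 ± 13.7 to 1.68 ± 1.13 RPKM (-2.99, SE 0.42, adjusted p = 0.00795).

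The cholangiocyte and ductular reaction list had 13 of 14 genes lower, also adjusted over the list alone (camera adjusted p = 2.26e-14, adjusted p = 0.133 with an estimated correlation). Sox9 fell by 1.42 to 0.3 ± 0.0881 RPKM (SE 0.14, adjusted p = 0.00197), Cd24 by 2.84, Prom1 by 1.18 and Epcam by 1.57. Krt19 fell by 2.32 to 1.77 ± 0.586 RPKM (SE 0.47, adjusted p = 0.0346) and Spp1 by 2.93 to 2.97 ± 1.67 RPKM (adjusted p = 0.0306), with these calls lost in 18 and 14 of 23 alternatives. In HepLPC replicate 2 the median of the duct list lay -0.176 from its group mean, in PBS replicate 1 -0.494 and in PBS replicate 2 0.479. Fetal liver and progenitor genes had 4 of 8 lower, also adjusted over the list alone (camera adjusted p = 0.00357, adjusted p = 0.133 with an estimated correlation), with Sox4 at -1.49 and Gpc3 at -1.66.

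Scar genes were lower in part. Of 21 fibrillar collagen and scar matrix genes 5 fell (16 adjusted over the list alone; camera adjusted p = 1.99e-09, adjusted p = 0.193 with an estimated correlation): Mgp, Col1a1 from 7.18 ± 3.32 to 1.14 ± 0.674 RPKM (-1.88, SE 0.32, adjusted p = 0.016), Col4a1 (-1.05), Fbln5 (-0.75) and Col3a1 (-0.92, SE 0.21, adjusted p = 0.0468). The Col3a1 call was lost in 21 of 23 alternatives. The list's medians in PBS replicate 1 and HepLPC replicate 2 lay -0.367 and -0.309 from their group means. Of 14 matrix proteases and inhibitors 4 fell (7 adjusted over the list alone; camera adjusted p = 9.38e-06, adjusted p = 0.182 with an estimated correlation): Mmp12 (-1.40), Timp2 (-1.19), Ctsk (-0.84) and Adamts2 (-0.91). Timp1 was at 9.22 ± 2.31 and 4.05 ± 1.72 RPKM (adjusted p = 0.0727) and Mmp2 at 8.72 ± 2.21 and 4.12 ± 1.28 RPKM (adjusted p = 0.0628). Of 13 myofibroblast markers 6 fell (11 adjusted over the list alone; camera adjusted p = 2.64e-07, adjusted p = 0.12 with an estimated correlation), with Loxl1 at -1.41, S100a6 at -1.68, Vim at -1.19 and Gas6 at -1.18, and the count was 1 after rescaling. Acta2 was at 4.11 ± 0.827 and 2.25 ± 0.413 RPKM (-0.65, SE 0.24, adjusted p = 0.21). TGF-beta signalling had 5 of 22 lower (8 adjusted over the list alone; camera adjusted p = 0.000692, adjusted p = 0.404 with an estimated correlation), Tgfb3 by 1.15, Tgfb2 by 0.93, Ctgf by 1.69 and Ltbp1 by 0.88 among them, while Tgfb1 was at 7.61 ± 0.795 and 4.77 ± 0.645 RPKM (adjusted p = 0.0738). The Ctgf call was lost in 18 of 23 alternatives and the Ltbp1 call in 18 of 22.

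The series title names apoptosis of hepatic stellate cells. Of 13 stellate cell markers 1 fell, Cygb, at -1.43, also adjusted over the list alone (camera adjusted p = 0.677). Desmin (Des) was at 3.04 ± 0.476 and 2.06 ± 0.387 RPKM (adjusted p = 0.18), Lrat at 11.9 ± 3.64 and 10.9 ± 3.07 RPKM (adjusted p = 0.83) and Pdgfrb at 3.51 ± 1.05 and 2.40 ± 0.988 RPKM (adjusted p = 0.465). Of 23 pro-apoptotic genes 1 fell, Tnfsf10, at -0.92 (4 adjusted over the list alone; camera adjusted p = 0.201), and none rose. Bax and Fas differed by -0.11 (SE 0.25, adjusted p = 0.837) and -0.71 (SE 0.17, adjusted p = 0.0557). None of 12 anti-apoptotic genes passed, also adjusted over the list alone (0 called; camera adjusted p = 0.163), and of 16 p53 targets 1 fell, Gadd45a, at -0.85, a call lost in 13 of 23 alternatives (4 adjusted over the list alone; camera adjusted p = 0.22). Fry placed the pro-apoptotic genes and the p53 targets lower after the cells (adjusted p = 0.018 and 0.0351), without setting them against the median of all genes, which was also lower, and the anti-apoptotic and stellate lists did not pass it (adjusted p = 0.0655 for both). Transcript levels of whole liver do not measure apoptosis or the cells it occurs in.

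Recruited and scar-associated macrophages had 6 of 11 markers lower, also adjusted over the list alone (camera adjusted p = 7.3e-07, adjusted p = 0.126 with an estimated correlation), Lyz2 by 2.27, Cd9 by 1.67, Gpnmb by 1.45 and Trem2 by 1.24. None of 13 Kupffer cell markers passed, also adjusted over the list alone (0 called; camera adjusted p = 0.427). In the list of neutrophils and mast cells 1 of 6 fell, Retnlg, at -1.04 (3 adjusted over the list alone; camera adjusted p = 0.0113, adjusted p = 0.133 with an estimated correlation). None of 7 MHC class II genes passed, also adjusted over the list alone except 1 (camera adjusted p = 0.0176, adjusted p = 0.403 with an estimated correlation). Without PBS replicate 1 and HepLPC replicate 2 the last 2 lists no longer passed camera (adjusted p = 0.0756 and 0.416). Of 19 chemokines and cytokines 2 fell (3 adjusted over the list alone; camera adjusted p = 0.677), Ccl21 by 2.42 and Cxcl16 by 1.23.

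The NRF2 list had 10 of 21 genes lower (18 adjusted over the list alone; camera adjusted p = 5.62e-12, adjusted p = 0.133 with an estimated correlation): Gstp1 fell by 3.03 to 71.8 ± 16.5 RPKM (SE 0.55, adjusted p = 0.0206), Nqo1 by 2.90 and Mt2A by 2.43. This count was 5 after rescaling and 1 without PBS replicate 1 and HepLPC replicate 2. Of 21 proliferation genes 2 fell, Rrm2 (-0.88) and Bub1 (-0.59) (13 adjusted over the list alone; camera adjusted p = 7.2e-07, adjusted p = 0.193 with an estimated correlation), and none after rescaling (0 called), while Mki67 was at 1.92 ± 0.464 and 0.855 ± 0.241 RPKM (adjusted p = 0.0569). In gluconeogenesis and glycolysis 3 of 17 fell, also adjusted over the list alone, where 2 others rose (camera adjusted p = 0.159): Aldoa (-0.81), Hk1 (-0.91) and Pkm (-0.81). Alternatives lost the calls of Pkm in 21 of 23 cases, Hk1 in 18 of 22 and Aldoa in 4 of 23, and those of Rrm2 and Bub1 in 19 and 18 of 22.

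Camera placed hepatocyte lists above the other genes with almost no single gene called, and most of these placings depended on the normalization. In urea cycle and amino acid catabolism (25 genes) and in fatty acid oxidation and ketogenesis (25 genes) none passed, also adjusted over the list alone (0 called in both), with camera adjusted p = 1.13e-07 and 7.3e-07 and adjusted p = 0.16 and 0.145 with an estimated correlation. The same held for secreted proteins and coagulation, with 0 of 24 called, also adjusted over the list alone (camera adjusted p = 9.15e-06, adjusted p = 0.12 with an estimated correlation), and for lipogenesis, with 0 of 17, also adjusted over the list alone (camera adjusted p = 3.54e-05, adjusted p = 0.28 with an estimated correlation). Lipogenesis lay -0.704 from the group mean in HepLPC replicate 2. Of 16 periportal genes 1 rose, Hsd17b13, a lipid droplet protein, from 104 ± 9.29 to 180 ± 14.2 RPKM (0.78, SE 0.14, adjusted p = 0.0185), also adjusted over the list alone (camera adjusted p = 2.45e-06, adjusted p = 0.12 with an estimated correlation). Of 17 pericentral genes 1 fell, Nkd1, at -0.76, a call lost in 20 of 22 alternatives (2 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.000611, adjusted p = 0.126 with an estimated correlation), and glutamine synthetase (Glul) was at 79.5 ± 14.9 and 118 ± 4.55 RPKM (adjusted p = 0.0648). Camera also placed cytochrome P450 drug metabolism, with 0 of 23 called (1 higher and 3 lower adjusted over the list alone), and bile acid genes, with 1 of 23 lower, Abcc3 at -2.09, also adjusted over the list alone, above the other genes (adjusted p = 0.0119 and 0.00357, adjusted p = 0.28 and 0.145 with an estimated correlation), but not after rescaling (adjusted p = 0.123 and 0.111) or with length trends removed (adjusted p = 0.18 and 0.0782). With quantile normalization secreted proteins and coagulation (adjusted p = 0.669), P450 drug metabolism (0.895), bile acid genes (0.449), lipogenesis (0.0627) and pericentral genes (0.0644) no longer passed camera. The urea cycle (0.00781), fatty acid oxidation (0.0256) and periportal lists (0.0147) still passed. Fry called 12 lists lower and 0 higher. Albumin (Alb) differed by 0.19 (SE 0.23, adjusted p = 0.703).

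The other genes among the largest falls were Defb1 (-2.57, SE 0.53), the glucuronosyltransferase Ugt2b7 (-3.17, SE 0.72) and Ifit1, an interferon-induced gene (-2.54, SE 0.38, adjusted p = 0.0106), which was at 5.03 ± 0.75 RPKM in PBS and 0.0334 ± 0.0383 RPKM in HepLPC livers. The Ugt2b7 call was lost in 20 of 22 alternatives, the Defb1 call in 19 of 23 and the Ifit1 call in 4 of 23. By the rule for named genes 7 rises were listed: Hes6 (1.13, SE 0.21), Olr59 (1.00), Sult1c2a (0.92), Sdr42e1 (0.92), Meiob (0.86), Hsd17b13 and Fahd1 (0.68). The call of Meiob was lost in 18 of 22 alternatives, and those of Sdr42e1, Olr59, Fahd1 and Sult1c2a in 15, 14, 14 and 13 of 23.

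**Figure D2:**
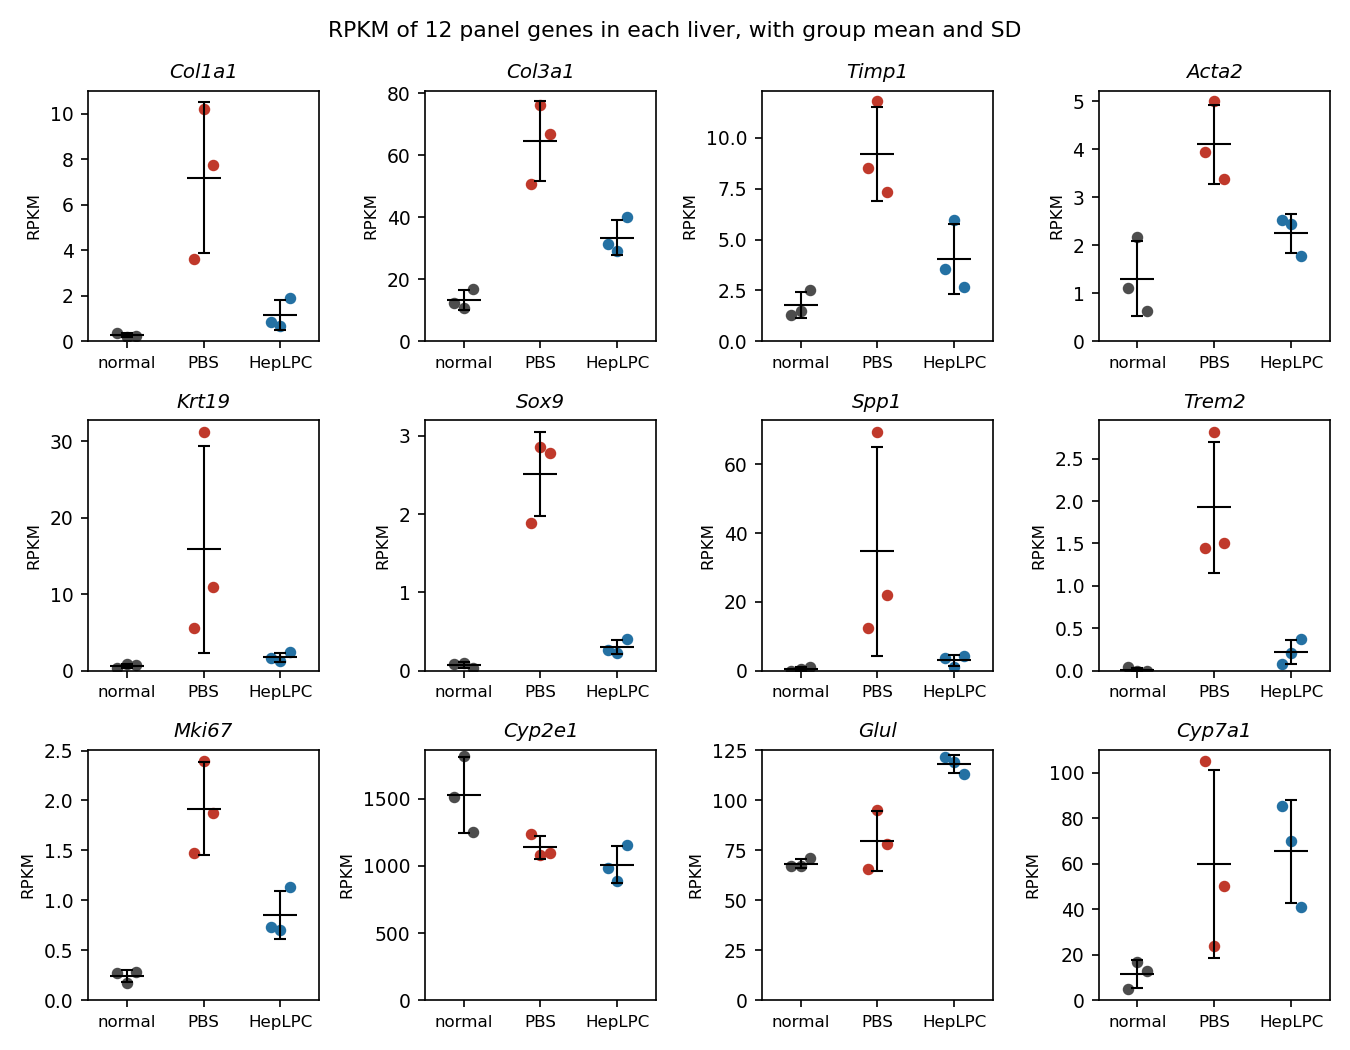
RPKM of 12 genes of the fixed panel in each liver of the 3 groups, with 1 point per liver, a line at the group mean and bars of 1 SD. Sox9 was at 2.51 RPKM in PBS and 0.3 RPKM in HepLPC livers, and Acta2 at 4.11 and 2.25 RPKM, a difference that did not pass the test.

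In all, limma called 341 genes between HepLPC and PBS livers, 15 higher and 326 lower, and the groups' values did not overlap for 18.4% of genes, against 10% by chance. The median log2 fold change of all genes was -0.145. After rescaling by the median of ratios 181 genes were called, 23 higher and 158 lower, and a fit of only these 2 groups called 86. The main fit takes 1 spread per gene for all 3 groups, so the normal livers enter the SE and p-values of this comparison. Fitted with only its own 2 groups, PBS against normal gave 1477 calls. Whether the spread was equal across groups was not tested. Leaving out normal replicate 1, 2 or 3 gave 225, 215 and 212 calls, PBS replicate 3 gave 90, and HepLPC replicate 1 or 2 gave 102 and 198.

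**Figure D3:**
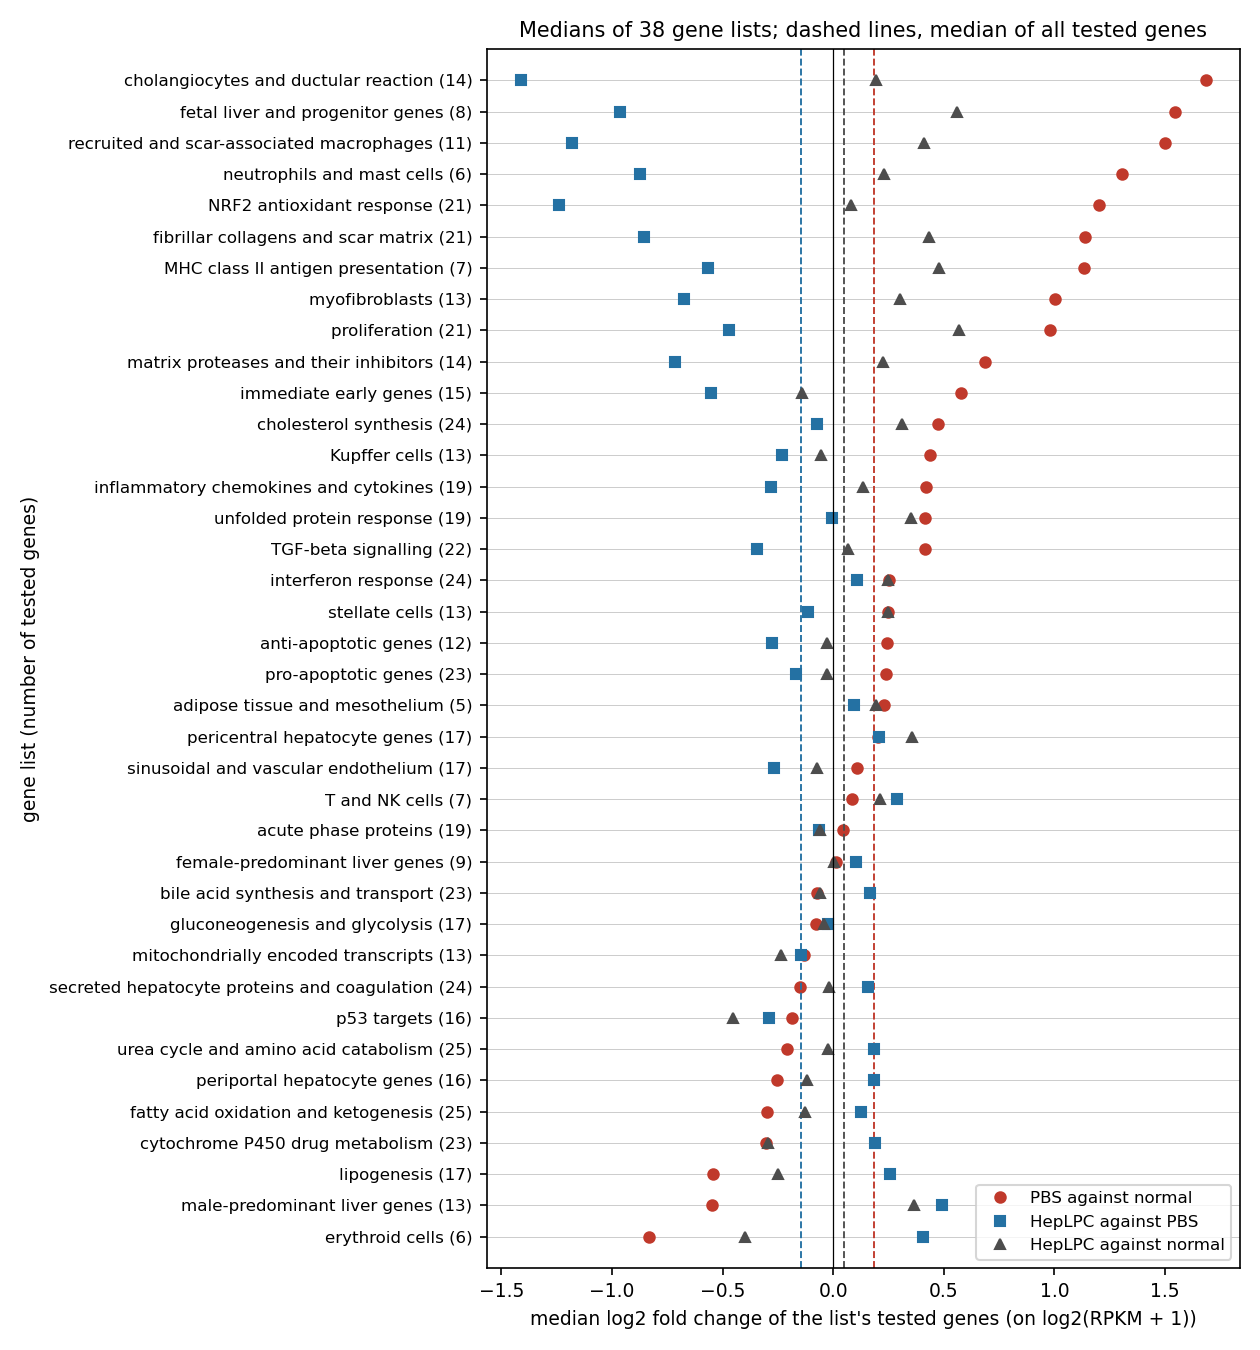
Median log2 fold change, on log2(RPKM + 1), of the tested genes of each of 38 lists in the 3 comparisons, with dashed lines at the median of all tested genes. The duct list lies at 1.68 in PBS against normal and at -1.41 in HepLPC against PBS, the ends of the range among these lists on those sides.

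The 3rd comparison, HepLPC against normal livers, asked how far the treated liver still differed from the healthy one. Here too the normal rats had no injection, so injury and injection cannot be told apart. Few genes passed. Mgp (1.65, SE 0.22), the mast cell protease Mcpt2 (2.75, SE 0.37), the ammonium transporter Rhbg (1.86, SE 0.26) and Prr32 (1.55, SE 0.21) were higher in HepLPC livers, each with adjusted p = 0.0464. Lepr, the leptin receptor, was lower, at 1.59 ± 0.233 RPKM in normal and 0.0851 ± 0.135 RPKM in HepLPC livers (-1.26, SE 0.14, adjusted p = 0.0273). Alternatives lost the call of Lepr in 13 of 22 cases, Mcpt2 in 18 of 23, Mgp and Rhbg in 19 of 23 and Prr32 in 20 of 23.

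Some lists still stood apart under camera at its preset correlation, while 0 passed with an estimated one. Fry placed proliferation higher and p53 targets lower (adjusted p = 0.0206 for both). It did not call scar matrix (adjusted p = 0.138), fatty acid oxidation (0.243) or cholesterol synthesis (0.243). Fibrillar collagens and scar matrix had 1 of 21 genes called, Mgp (6 adjusted over the list alone), and lay above the other genes (camera adjusted p = 2.15e-07, adjusted p = 0.378 with an estimated correlation), with a median of 0.43. Proliferation had 0 of 21 called (16 adjusted over the list alone) and a median of 0.57 (camera adjusted p = 5.48e-16, adjusted p = 0.203 with an estimated correlation). The p53 targets had 0 of 16 called (3 lower adjusted over the list alone) and a median of -0.45 (camera adjusted p = 2.27e-08, adjusted p = 0.102 with an estimated correlation). Fatty acid oxidation and ketogenesis, with 0 of 25 called, also adjusted over the list alone, had a median of -0.13 (camera adjusted p = 6.61e-06, adjusted p = 0.281 with an estimated correlation). Cholesterol synthesis had 0 of 24 called (8 adjusted over the list alone) and a median of 0.31 (camera adjusted p = 0.000453, adjusted p = 0.458 with an estimated correlation). That list's median lay 0.371 from the group mean in HepLPC replicate 3, against -0.13 and -0.199 in replicates 1 and 2. The duct list, with 0 of 14 called, also adjusted over the list alone, did not pass camera (adjusted p = 0.153), and neither did the NRF2 list, with 0 of 21 called and 2 adjusted over the list alone (adjusted p = 0.153). Krt19 differed by 0.75 (SE 0.47, adjusted p = 0.71), Col1a1 by 0.72 (SE 0.32, adjusted p = 0.533) and Cyp7a1 by 2.48 (SE 0.55, adjusted p = 0.21). A missed threshold does not show that these levels were equal.

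In all, limma called 9 genes, 5 higher and 4 lower, of which the 5 above have gene symbols, and 816 higher and 220 lower had an unadjusted p under 0.05. Leaving out normal replicate 1, 2 or 3 gave 4, 4 and 1 calls. Leaving out PBS replicate 1, 2 or 3 gave 5, 14 and 6, and HepLPC replicate 1, 2 or 3 gave 4, 10 and 1. This small count thus varied with the libraries used. The PBS libraries enter this comparison only through the estimate of spread.

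The last comparison asked whether genes changed in the PBS livers changed back after the cells. Of the genes called in PBS against normal, 324 were also called in HepLPC against PBS in the opposite direction, 316 higher and then lower and 8 lower and then higher. In the same direction there were 0. Independent lists of these sizes would share 33.9 and 0.1. With the smallest larger adjusted p came Mgp, Spint1, a protease inhibitor of epithelia (2.04 and -1.77), the glutathione peroxidase Gpx3 (2.70 and -2.10), Pdzk1ip1 (-1.62 after the cells), Prr15l (1.54 and -1.26), Cygb (1.86 and -1.43), Emp1 (2.21 and -1.81), Ppp1r1b (1.80 and -1.46), Smoc2, a matrix protein (1.95 and -1.49), and Sox4 (2.06 and -1.49). Of the 1262 genes called in PBS against normal, 8 were also called in HepLPC against normal, 4 higher and 4 lower in both. That comparison called only 9 genes in all, so this count was capped and does not measure a return to normal levels.

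**Figure D4:**
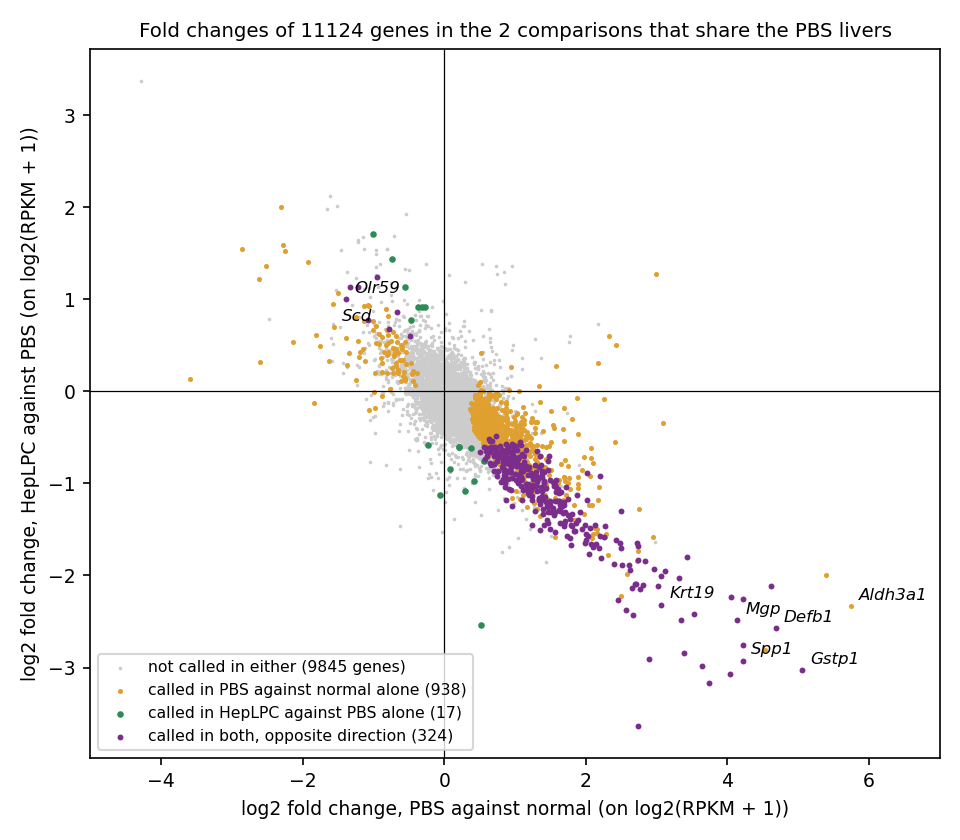
Log2 fold change of each of 11124 genes in PBS against normal (horizontal axis) and in HepLPC against PBS (vertical axis), both on log2(RPKM + 1), coloured by which comparison called the gene. The 324 genes called in both lie in the 2 quadrants of opposite sign, and since both axes use the PBS livers, part of the slope arises by chance.

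Both comparisons use the same PBS libraries, so their chance errors have opposite signs. The covariance of the fold changes across all 11124 genes was -0.1272. Its median was -0.0322 in 100 simulated draws with no effect (lowest -0.1408) and -0.0315 in 100 draws that kept the PBS effect (lowest -0.1449). The correlation was -0.7554, against medians of -0.567 and -0.2486, and the lowest with the PBS effect kept was -0.5795. With no effect it ranged from -1 to 1, ends reached by construction where a draw kept the residuals of 1 group together, since these sum to 0 and leave the other group means exact opposites. Of the genes called higher in PBS livers 98.8% had a negative change after the cells, against a median of 63.2% and at most 88.5% in the draws that kept the PBS effect. The simulated median of opposite calls was 0 in both, but 5 of the 100 draws that kept the PBS effect reached 324 or more. The PBS libraries are too few to be split into parts of at least 2, so part of the excess may come from the shared libraries. Opposite calls numbered 169 after rescaling and 75 in fits of only the 2 groups compared. Leaving out normal replicate 1, 2 or 3 gave 205, 204 and 196, PBS replicate 3 gave 89, and HepLPC replicate 1 or 2 gave 99 and 189.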

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

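The alternatives on recovered reads, on rescaling, on gene length and on leaving out both departing libraries were tests chosen only after the results were seen. No named gene reversed direction where called (0 of 138 in PBS against normal, 76 in HepLPC against PBS and 5 in HepLPC against normal). Of these calls 57, 14 and 0 passed in every alternative run. The cause of the changes below was not tested. Only a stricter threshold makes a count smaller by construction. Fits with fewer libraries moved counts both ways: with only the 2 groups fitted, calls rose to 1477 in PBS against normal. In HepLPC against PBS they fell to 86.

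Calls between PBS and normal livers numbered 714 with quantile normalization, 568 with a filter of 5 RPKM, 468 at an adjusted p under 0.01, 170 for a tested fold above 1.5, 800 with limma-voom scaled by the median of ratios, 806 with RPKM rescaled by the median of ratios and 3168 without PBS replicate 1 and HepLPC replicate 2. Between HepLPC and PBS livers they numbered 164 with a pseudocount of 0.01, 213 with quantile normalization, 106 with the filter of 5 RPKM, 86 with only the 2 groups fitted, 79 at 0.01, 22 for the tested fold, 140 with limma-voom scaled by the median of ratios and 181 with rescaled RPKM. Opposite calls in the same order numbered 157, 193, 101, 75, 78, 22, 134 and 169.

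Calls between HepLPC and normal livers numbered 3 with quantile normalization, 3 with the length trend removed and 16 without both departing libraries. They numbered 0 with no filter, 0 with the filter of 5 RPKM, 0 at 0.01, 0 for the tested fold, 0 with limma-voom on library totals and 0 with limma-voom scaled by the median of ratios, where limma on RPKM gave 9 and 816 higher and 220 lower genes had an unadjusted p under 0.05.

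With the replicate block, which takes the replicate numbers of the labels as a factor, the counts were 787, 198 and 1 in the 3 comparisons and 192 opposite calls. Correlations of residuals between libraries of the same number ranged from -0.412 to 0.31. They cannot decide whether the numbers pair the samples. Residuals sum to 0 within a group, and PBS replicate 1 departed together with HepLPC replicate 2.

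Leaving out 1 library in turn gave 562 to 1809 calls between PBS and normal, 90 to 398 between HepLPC and PBS, 1 to 14 between HepLPC and normal, and 89 to 375 opposite calls. Camera with an estimated correlation called 0 lists in PBS against normal, 0 in HepLPC against PBS and 0 in HepLPC against normal, where the preset correlation gave 24, 24 and 18. Fry called 22, 12 and 5, of which 19, 0 and 4 were higher. Between HepLPC and PBS livers camera called 12 lists higher, but 4 with quantile normalization and 7 with rescaled RPKM. Of the 1262 and 341 genes, 634 and 171 were also called after rescaling. The alternatives for count files with DESeq2 and edgeR were not run. The files hold RPKM, and of the count-based fits only limma-voom was run on the recovered reads. Genes that reached 1 RPKM in fewer than 3 libraries were not tested.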

Other observations

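The tests of marker scores, of lipogenesis and of clock genes were chosen only after the results were seen, as were rescaling and the removal of length trends as alternatives. Lists not described with the comparisons are given first.

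Between PBS and normal livers, male-predominant liver genes had 2 of 13 lower, also adjusted over the list alone, and lay below other genes (camera adjusted p = 1.71e-06, adjusted p = 0.121 with an estimated correlation). Between HepLPC and PBS livers 0 of 13 were called (6 higher adjusted over the list alone), with camera adjusted p = 1.99e-09 and adjusted p = 0.12 with an estimated correlation. The list's medians were -0.55 and then 0.49. Single libraries lay up to nearly as far from their own group mean, at 0.295 in PBS replicate 2, -0.49 in PBS replicate 3 and 0.346 in HepLPC replicate 2. Of 9 female-predominant genes 1 rose in PBS livers, Cyp17a1, at 1.11 (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.449, placed below other genes although mean and median were positive). After the cells 0 were called, also adjusted over the list alone (camera adjusted p = 0.295), with a median of 0.10 and a mean of -0.30. Of 15 immediate early genes 4 rose in PBS livers (6 adjusted over the list alone; camera adjusted p = 0.0441, adjusted p = 0.41 with an estimated correlation) and 2 fell after the cells, Klf6 by 0.99 and Fosl2 by 0.98, the latter lost in 19 of 22 alternatives (7 adjusted over the list alone; camera adjusted p = 6.03e-05, adjusted p = 0.145 with an estimated correlation). Of 13 mitochondrially encoded transcripts 0 were called in either comparison, also adjusted over the list alone (camera adjusted p = 0.00149, adjusted p = 0.272 with an estimated correlation, then 0.473), and the 1st placing was lost with quantile normalization (adjusted p = 0.863).

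Acute phase proteins had 2 of 19 higher and 1 lower in PBS livers, also adjusted over the list alone (camera adjusted p = 0.114, placed below other genes with a positive median and mean), and 1 lower after the cells, Lcn2 (2 adjusted over the list alone; camera adjusted p = 0.397). Of 24 interferon response genes 1 rose, Ifi47, at 1.27, also adjusted over the list alone (camera adjusted p = 0.777), and 1 fell after the cells, Ifit1 (2 adjusted over the list alone). That list had a median of 0.11 and a mean of -0.04 after the cells and lay above other genes (camera adjusted p = 0.0244, adjusted p = 0.548 with an estimated correlation), but not with quantile normalization (adjusted p = 0.149). Of 19 unfolded protein response genes 2 rose in PBS livers, Hsp90b1 (0.64) and Asns (0.83), lost in 13 of 23 and 15 of 22 alternatives, also adjusted over the list alone (camera adjusted p = 0.184), and 0 were called after the cells, also adjusted over the list alone (camera adjusted p = 0.323). Of 17 gluconeogenesis and glycolysis genes 3 rose and 1 fell in PBS livers (4 and 4 adjusted over the list alone). Their median was -0.08 and their mean 0.03, and camera placed them below other genes (adjusted p = 0.0221, adjusted p = 0.122 with an estimated correlation), but not with quantile normalization (adjusted p = 0.519). Of 24 cholesterol synthesis genes 0 were called after the cells, also adjusted over the list alone (camera adjusted p = 0.203).

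Of 17 endothelial markers 2 rose in PBS livers, Vwf (0.89) and Aqp1 (0.95), the latter lost in 19 of 23 alternatives, also adjusted over the list alone (camera adjusted p = 0.936), and 0 were called after the cells (1 lower adjusted over the list alone; camera adjusted p = 0.233). Of 7 T and NK cell markers 0 were called in either, also adjusted over the list alone (camera adjusted p = 0.47, then 0.0307, adjusted p = 0.403 with an estimated correlation). Of 6 erythroid markers 0 were called in either, also adjusted over the list alone (camera adjusted p = 1.86e-05, adjusted p = 0.122 with an estimated correlation, then 0.0176, adjusted p = 0.403 with an estimated correlation), with a median of -0.83 and then 0.40. Single libraries lay as far from their own group mean in the erythroid list, 0.839 in normal replicate 1, 0.53 in PBS replicate 2 and -0.672 in PBS replicate 3. With quantile normalization the T and NK cell and erythroid placings after the cells were lost (adjusted p = 0.0786 and 0.0764). Of 5 adipose and mesothelial markers 1, Msln, rose by 2.57 and fell by 2.38, also adjusted over the list alone (camera adjusted p = 0.479, then 0.846). Too small for camera were B and plasma cells, with 2 of 4 higher in PBS livers, Jchain (1.87) and Fcrla (0.72), smooth muscle with 0 of 3 called, pancreas with 1 of 2 lower, Cela1, and skeletal muscle with 0 of 1 called. After the cells none of these 10 genes was called by limma over all genes. Adjusted over the list alone, 1 pancreas gene was higher and 1 skeletal muscle gene lower.

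Between HepLPC and normal livers camera also called fetal liver and progenitor genes (adjusted p = 0.000658, adjusted p = 0.203 with an estimated correlation), recruited macrophages (0.00905, adjusted p = 0.378 with an estimated correlation), stellate cells (0.0214, adjusted p = 0.345 with an estimated correlation), myofibroblasts (0.037, adjusted p = 0.432 with an estimated correlation), neutrophils and mast cells (0.0406, adjusted p = 0.281 with an estimated correlation), pericentral genes (0.00763, adjusted p = 0.281 with an estimated correlation), MHC class II (0.0106, adjusted p = 0.444 with an estimated correlation) and the unfolded protein response (0.00905, adjusted p = 0.426 with an estimated correlation) above other genes. Below other genes were erythroid markers (0.0028, adjusted p = 0.378 with an estimated correlation), P450 enzymes (0.000356, adjusted p = 0.281 with an estimated correlation), lipogenesis (0.000497, adjusted p = 0.437 with an estimated correlation), periportal genes (0.00905, adjusted p = 0.281 with an estimated correlation) and mitochondrially encoded transcripts (0.000893, adjusted p = 0.378 with an estimated correlation). Without both departing libraries lipogenesis, myofibroblasts, neutrophils and mast cells, macrophages and the unfolded protein response no longer passed (adjusted p = 0.218, 0.236, 0.236, 0.338 and 0.227).

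The first pattern weighed was the 324 genes called in opposite directions. With each library's trend on gene length removed the count was 283, which argues against that trend as the whole cause. A like loss of every cell type other than hepatocytes is argued against in part by the bile duct score. It fell more than the endothelial score by -1.27 (SE 0.23). The duct list was chosen after the results were seen and has the lowest median of the 38, so the choice favoured this outcome. Macrophage and myofibroblast scores also fell more than the endothelial one (-0.71, SE 0.21, and -0.53, SE 0.15). Kupffer and stellate scores did not (0.01, SE 0.29, and 0.10, SE 0.10). The shared PBS libraries stay open as a possible explanation of part of the count: 5 of 100 draws with the PBS effect kept and none of the cells reached 324, though the bound written before this test was run asked for none, and the reading of 5 as open was set after it was seen. All 5 were among the 30 draws, divided so afterwards, that put both departing libraries in 1 group. The 70 with these in different groups gave at most 2. Those of the 70 with 1 in PBS and the other in HepLPC, as in the real layout, gave at most 1. An effect of the cells stays open beside the shared libraries.

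The second pattern was the excess of higher calls in PBS livers, 91.7% of 1262. Library scaling could account for part of it: after rescaling by the median of ratios the share was 65.8%, between bounds of 60% and 75% that were written before this test was run but after the files were seen. Scaling and a true excess of higher genes cannot be told apart here, since no external standard was used.

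The third pattern was the joint departure of PBS replicate 1 and HepLPC replicate 2, whose deviations correlated at 0.608 across genes, which are not independent replicates. With length trends removed the correlation was 0.499, which argues against loss of long transcripts as the whole cause. Another time of day stays open, with the clock genes at percentile 91.97 in the lower library: the bound, set after the values were seen, was missed, but 3 libraries without the departure lay at 98.84, 99.61 and 99.67, so the test did not separate the 2 libraries and its first reading, an exclusion, was withdrawn. A lower lipogenic state was not decided. The lipogenesis list lay at percentile 2.55 in the higher library, PBS replicate 1, just above the written bound. A margin for simulation error added afterwards turned its exclusion into an open reading. Normal replicate 1, without the departure, lay at 0.01. The list's median deviation was lower in PBS replicate 2 (-0.0586) than in PBS replicate 1 (-0.0498). This test thus did not separate the 2 libraries, and no reading is drawn from it. A difference in sequencing depth was not tested. HepLPC replicate 3 had the fewest recovered reads, 17.4 M, and no such trend, while the departing libraries had 17.8 M (PBS replicate 1) and 19.3 M (HepLPC replicate 2). Deviations sum to 0 within a group, so the fall in HepLPC replicate 2 pushes replicate 3 the other way, and this decides nothing. No biological explanation named by the design was tested.

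With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real split called 1262 genes in PBS against normal and the highest other 0, 341 and 1 in HepLPC against PBS, and 9 and 1 in HepLPC against normal, each being the 1 split of 10 to reach its count. For lists the values were 24 and 22, 24 and 18, and 18 and 13. For opposite calls 100 of the 840 possible splits into 3 groups were drawn, and the real one gave 324 and the highest other 2. Most other splits mix the groups, so group differences enter their residual spread and lower their calls. The splits therefore show only that the labelled groups stand apart, and cannot exclude chance as a source of the opposite calls.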
